A study of Mus musculus with 7 samples.

How the data were processed

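Gene expression was measured in CD11c-positive cells enriched from mouse spleen by magnetic sorting on day 7 after allogeneic hematopoietic stem cell transplantation, on 4 wild-type and 3 Atg16l1 hypomorph arrays, all with the C57BL/6J background per the labels. The description of the experiment gives an age of 8 weeks and the sample protocol 9 weeks at collection. RNA was extracted with Trizol, and 100 ng of total RNA was labelled and hybridized to an Affymetrix GeneChip (Mouse430A), 1 per sample. The authors deposited 1 log2 value per probe set and array, and their notes name Affymetrix Power Tools. The version, the summary method, the background correction and the normalization between arrays are not given in the sources used here. The values ran on a log2 scale with array medians from 5.46 to 5.53 and nearly equal quartiles, so they had been normalized between arrays. Which normalization was used stays unknown. The mean correlation of an array with the others was 0.990 to 0.993, and 4.74% to 7.07% of probe sets had identical values in a pair of arrays.

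Of 22690 probe sets, 64 control probe sets were left out and 1 had no value, leaving 22625. Gene names came from the deposited annotation of the array, updated by Entrez identifier in a table of RefSeq genes of the GRCm38.p6 assembly. Of the tested probe sets, 20379 named 1 gene (12393 distinct genes, with 20350 of these probe sets found in the table), 691 named several and 1555 named none. No coordinates are given, since the array files name no genome build, and the table served for names and gene order.

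The deposited values were used as they were. Hypomorph and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust settings, 2 group means, no block), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05 on the adjusted p. Single measures were compared with exact two-sided permutation tests over the 35 splits of 7 arrays into 4 and 3, for which 0.0286 is the smallest p. The tests of the chromosome 1 difference and of the SD of list medians were one-sided over these splits. They counted the splits with a value at least as large as the real one. The exact permutation p of correlations between lists did not come from these 35 splits and can be smaller. Replicate numbers were not used as pairs, because no label pairs the arrays.

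The comparison, the alternatives, the lists and the rule for naming genes were fixed before the data were examined. The rule named Atg16l1, then 11 genes of dendritic cell activation and autophagy (Tnfaip3, Cd80, Cd86, Cd40, Il12b, Tnf, Il6, Il1b, Sqstm1, Lamp1 and Lamp2), then 12 genes in each direction. These 12 were to be those with the largest change among probe sets past the threshold that name 1 gene and whose groups do not overlap, filled up from the smallest unadjusted p where too few passed. In each list described, up to 4 members with the smallest p were named. S100a8, Cela1, Cela3b, the Ugt1a probe sets and the other genes outside the rule were chosen after their values were seen.

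A total of 36 lists was tested, with 770 listed and 656 measured genes. The function lists were costimulation and maturation, MHC class II presentation, MHC class I presentation, NF-kB and A20 feedback, inflammatory cytokines, chemokines, type I interferon response, interferon gamma response, autophagy machinery, lysosome, unfolded protein response, NRF2 antioxidant response, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, pattern recognition and inflammasome, immediate early and heat shock, cell death and p53, ribosomal proteins, and Y chromosome and Xist. The cell type lists were pan, CD8 lineage, CD11b lineage and plasmacytoid dendritic cells, T cells, cytotoxic lymphocytes and NK cells, B cells, plasma cells, monocytes, red pulp macrophages, neutrophils, erythroid cells, megakaryocytes and platelets, basophils and mast cells, and stroma and endothelium. Each gene entered with the probe set of highest mean. Lists were tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over the 36 lists. A further 6 lists were drawn up after the data were seen: pancreatic acinar cell, pancreatic islet cell, liver and gut epithelium, xenobiotic and antioxidant targets, eosinophil, and nuclear retained RNA.

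The limma and camera steps were tested on simulated data with 4 and 3 arrays in 10 runs, with 200 of 22625 probe sets changed in each. Of changed probe sets, 44.1% were recovered at a log2 change of 0.5, 91.9% at 1 and 99.1% at 2, and 4.99% of the calls were false. A list of 30 genes shifted by 0.3 was called in 10 of 10 runs and an unshifted list in 0. The simulated noise was independent between probe sets, whereas real lists had estimated correlations of up to 0.851 (cell cycle). The runs therefore do not show how often a list of correlated genes is called without a shift. They also do not give the recovery to be reached in the real data.

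The alternatives were quantile normalization, centring each array on its median, leaving out the lowest 40% of probe sets by mean, eBayes with trend and robust settings, array weights, the replicate number as a block, adding 32 to the linear value, leaving out each array in turn, the mean over all probe sets of a gene, the estimated correlation, and a window of 10 instead of 20 megabases around Atg16l1. Wild-type replicate 4 is the only array with its number, so it adds nothing to the comparison in the fit with the block. The log2 change of a probe set with the block therefore equals that without this array, and the 2 settings are not independent. Leaving out the 2 wild-type arrays with the most acinar transcripts, and taking the acinar level as a covariate, were chosen after seeing the data. Whether the arrays came from separate animals, and which donors were used, is not given in the sources used here.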

Results

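Gene expression was measured in CD11c-positive cells enriched from the spleens of mice that had received an allogeneic hematopoietic stem cell transplant, a transplant from a genetically different donor. CD11c is a surface integrin by which dendritic cells, the main antigen-presenting cells of the spleen, are commonly isolated. Spleens were taken on day 7 after the transplant, and 4 arrays were labelled wild type and 3 Atg16l1 hypomorph, all on the C57BL/6J background. Atg16l1 encodes a protein needed to attach LC3 to the membranes of forming autophagosomes, and a hypomorph keeps part of the gene's function. The comparison asks which transcripts differ between these labels. Whether the labelled genotype is that of the recipient, the donor or both, and so whether the measured cells carry the allele, is not given in the sources used here. Each array gave 22625 probe set values on a log2 scale, with array medians between 5.46 and 5.53. The number of arrays limits the precision. The labels do not say whether each array came from a separate animal, so p-values measure only the spread between these 7 samples.

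Atg16l1 itself was measured by 1 probe set. Its log2 value was 7.30 ± 0.0924 (SD, n = 4) in wild type and 6.86 ± 0.0912 (SD, n = 3) in the hypomorph, a level 1.36-fold lower. All 3 hypomorph arrays lay below all 4 wild-type arrays, and the exact two-sided permutation p was 0.0286, the smallest that 7 arrays split into 4 and 3 can give. In the limma fit over all probe sets the log2 change was -0.45, with a 95% confidence interval from -0.63 to -0.26 and an adjusted p = 0.462, so it did not pass the threshold of 0.05. Where this probe set lies relative to the altered part of the gene was not analysed here, so the lower signal is a limited check of the labels.

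Of the 5 probe sets closest to the threshold, those with the largest log2 changes belonged to the Ugt1a cluster, whose genes encode enzymes that attach glucuronic acid to bilirubin, steroids and drugs. A set of 3 probe sets, each annotated to 8 Ugt1a genes and therefore to none alone, read between 5.21 and 5.96 times higher in the hypomorph. The one with the smallest p was at 9.29 ± 0.157 (SD, n = 4) in wild type and 11.71 ± 0.544 (SD, n = 3) in the hypomorph. The others read 7.87 ± 0.148 in wild type and 10.44 ± 0.632 in the hypomorph, and 8.20 ± 0.0953 and 10.58 ± 0.617. These probe sets were singled out after their values were seen. Their adjusted p were 0.0694, 0.0814 and 0.0826, just outside the threshold, although every hypomorph array was above every wild-type array. In the gene order of the GRCm38.p6 assembly, the Ugt1a genes lie on chromosome 1, the chromosome of Atg16l1, and the nearest of them is 4 protein-coding genes away from it.

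Among probe sets that name 1 gene, Pcmtd1 and Cdk12 were the closest to the threshold. Pcmtd1, which encodes a protein with a methyltransferase-like domain, was at 6.00 ± 0.125 in wild type and 6.98 ± 0.0758 in the hypomorph, 1.97-fold higher. Cdk12, a kinase that phosphorylates RNA polymerase II during elongation, was at 5.90 ± 0.110 and 6.86 ± 0.107, 1.94-fold higher. For each gene this was the probe set with the largest change. The log2 changes of the 3 probe sets of Pcmtd1 ran from 0.27 to 0.98, and the 2 of Cdk12 had 0.33 and 0.95. The probe sets with the largest change both had an adjusted p = 0.0694 in the limma fit. With the 3 Ugt1a probe sets they made up the 5 probe sets whose adjusted p was under 0.1, and all 5 were higher in the hypomorph.

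**Figure D1:**
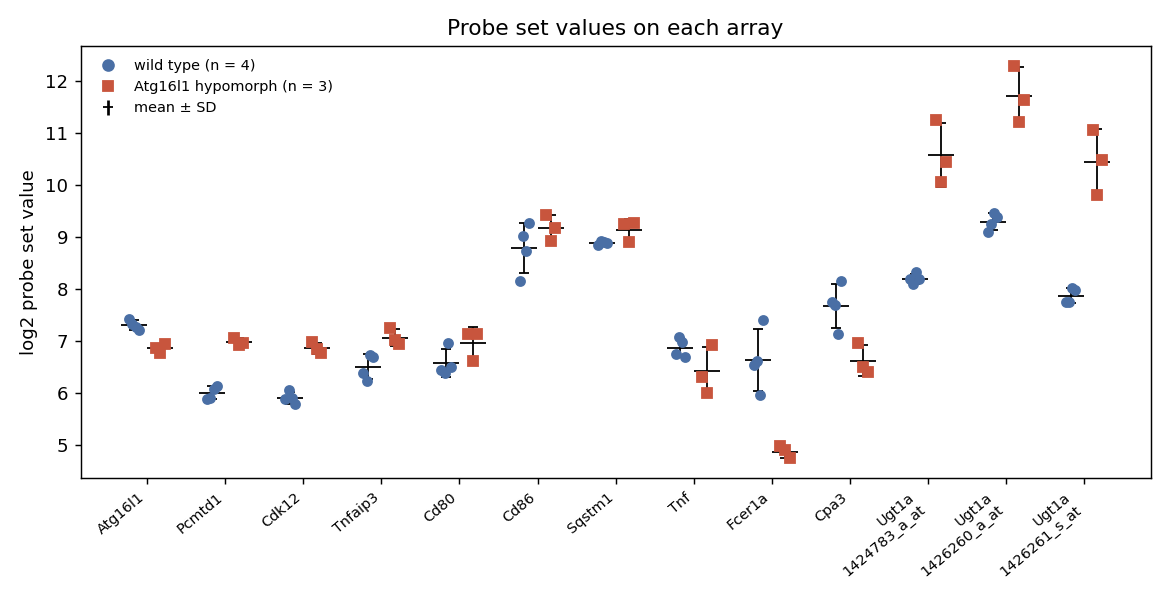
Log2 values of 13 probe sets on each array, with wild-type arrays as circles, Atg16l1 hypomorph arrays as squares, and black marks for the mean ± SD of each group. The hypomorph arrays lie below the wild-type arrays for Atg16l1, Fcer1a and Cpa3, and above them for Pcmtd1, Cdk12, Tnfaip3 and the 3 Ugt1a probe sets.

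No probe set passed an adjusted p of 0.05 in the limma fit, with 0 higher and 0 lower among the 22625 tested. At an unadjusted p under 0.05 there were 984 probe sets higher and 755 lower in the hypomorph, 1739 together, against 1131.25 that chance would give on average. The excess does not exclude chance, since 4 of the 35 splits of the arrays, the real one among them, gave at least 1739. The highest of the others gave 2047. Probe sets whose groups did not overlap numbered 1261, or 5.57%, where chance gives 5.71%. Centring each array on its median, or letting the variance follow the mean with robust settings, brought all 5 of the probe sets above under the threshold, with adjusted p from 0.0430 to 0.0462. With single arrays left out, the adjusted p of Pcmtd1 and Cdk12 ran from 0.110 to 0.431. Without hypomorph replicate 1 the unadjusted counts were 598 higher and 497 lower, without wild-type replicate 2 there were 431 lower, and without hypomorph replicate 2 there were 1578 lower. An adjusted p under 0.05 was reached by 1 probe set without wild-type replicate 3, which names no gene and is not one of the 5 above. It was also reached by 1 Ugt1a probe set without hypomorph replicate 1 and by 2 without hypomorph replicate 2. All of these were higher. The genes named next were therefore taken in order of their unadjusted p among probe sets without overlap, and none of them passed the threshold.

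Of the 12 genes so named as higher, Il6st, Papola and AY036118 showed log2 changes of 0.74, 0.77 and 0.66 after Pcmtd1 and Cdk12. Il6st encodes gp130, the signalling chain shared by receptors of the interleukin-6 family, and read 4.37 ± 0.159 in wild type and 5.11 ± 0.184 in the hypomorph. Papola encodes a poly(A) polymerase and read 7.26 ± 0.126 and 8.03 ± 0.239. Ndrg1, a stress-responsive gene, and Nabp1, a single-stranded DNA-binding protein of the DNA damage response, had log2 changes of 0.61 and 0.62. Hdlbp, Taok1, Fmr1, Max and Kif5b had log2 changes between 0.42 and 0.56. Of these 12 genes, 10 had several probe sets on the array, and for 6 of the 10 (Ndrg1, Papola, Hdlbp, Kif5b, Fmr1 and Taok1) at least 1 other probe set had the opposite sign. All 3 probe sets of Nabp1 were higher, by 0.61 to 0.72, as were all 3 of Il6st, by 0.13 to 0.74.

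Of the 12 genes named as lower, Fcer1a and Cpa3 had the largest log2 changes, -1.76 and -1.06. Fcer1a encodes the alpha chain of the high-affinity IgE receptor and read 6.63 ± 0.598 in wild type and 4.87 ± 0.115 in the hypomorph, 3.38-fold lower. Cpa3, mast cell carboxypeptidase A, read 7.68 ± 0.420 and 6.62 ± 0.3, 2.08-fold lower. Rgs18, a regulator of G-protein signalling of blood cells, had a log2 change of -0.61 and was lower with both of its probe sets. Mnd1, Tiam1, Ly6d, Tspan2, Carmil1, Entpd5, Atg16l1, Mbnl3 and Stk26 had log2 changes between -0.56 and -0.42. Of the 12, 5 had several probe sets, and only for Tspan2 did another probe set have the opposite sign.

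Among genes of dendritic cell activation fixed beforehand, Tnfaip3 showed the clearest difference. Tnfaip3 encodes A20, an enzyme that restrains NF-kB signalling, and read 6.50 ± 0.238 (SD, n = 4) in wild type and 7.06 ± 0.163 (SD, n = 3) in the hypomorph. It was 1.47-fold higher and higher in all 3 hypomorph arrays than in any wild-type array (limma adjusted p = 0.644). The costimulatory ligands Cd80 and Cd86 had log2 changes of 0.39 (95% confidence interval -0.03 to 0.81) and 0.37 (-0.23 to 0.97), and Cd40 had a change of 0.04 (-0.31 to 0.38). Other probe sets of these genes gave 0.43 (without overlap), 0.08 and -0.09 for Cd80, 0.11 for Cd86 and 0.11 for Cd40, so the probe sets of Cd80 differed in sign and those of Cd86 in size. The cytokine genes Il12b, Tnf, Il6 and Il1b had changes of -0.08, -0.46, 0.17 and 0.05, with intervals that all included 0, and another probe set of Il12b gave -0.39. The Il12b probe set with -0.08 read only 3.13 to 3.47, near the lower quartiles of the arrays (3.31 to 3.39), so it says little about this gene. Single arrays moved the changes of the cytokine genes, Cd86 and Cd40. Il6 was at -0.23 without hypomorph replicate 1 and 0.50 without hypomorph replicate 2, Il1b at -0.49 without hypomorph replicate 3 and 0.33 without hypomorph replicate 1, and Tnf at -0.71 without hypomorph replicate 3 and -0.25 without hypomorph replicate 2. Il12b ran from -0.13 to -0.01 without hypomorph replicates 3 and 2, Cd86 from 0.16 to 0.53 without wild-type replicates 1 and 4, and Cd40 from -0.10 to 0.12 without hypomorph replicate 1 and wild-type replicate 2. Tnfaip3 stayed between 0.47 and 0.63 and Cd80 between 0.30 and 0.56. Sqstm1, which encodes the autophagy cargo receptor p62, had a change of 0.25 (0.02 to 0.49), from 8.88 ± 0.0345 to 9.14 ± 0.210. The lysosomal membrane genes Lamp1 and Lamp2 had changes of 0.17 and 0.10, or 0.09 without hypomorph replicate 1, 0.28 without hypomorph replicate 2 (Lamp1) and 0.03 without wild-type replicate 1 (Lamp2), and the other probe sets of Lamp2 gave 0.11 to 0.19. None of these 11 genes passed the threshold over all probe sets.

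Of 36 gene lists fixed beforehand, 21 on functions and 15 on cell types, 9 ranked higher in the hypomorph relative to all other genes and 6 ranked lower in the camera test with a preset correlation of 0.01 between genes. None of these 15 calls held when the correlation was estimated from the data, and fry, which tests whether the genes of a list move, called 0 lists in either of its forms. The adjusted p with an estimated correlation is given beside each of the 15 called lists. Most other lists are given with the preset correlation alone, and with an estimated correlation 0 of the 36 lists were called. No member of any list passed the threshold over all probe sets, so changes of single members are given as values.

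Lists on lysosomes and autophagy ranked higher. In the lysosome list, 30 of 34 measured genes had a positive change, with a median log2 change of 0.17 (camera adjusted p = 7.91e-06, and adjusted p = 0.653 with an estimated correlation). Its members with the smallest p were the protease genes Ctsl (0.47) and Lgmn (0.51), the cholesterol carrier Npc2 (0.26) and Laptm4a (0.50). In the autophagy list, 21 of 30 were positive with a median of 0.05 (adjusted p = 0.00739, and adjusted p = 0.593 with an estimated correlation). It was led by the initiating kinase Ulk1 (0.32), Uvrag (0.49), Sqstm1 (0.25) and Gabarapl1 (0.24). No member of either list passed when adjusted over the list alone. The lysosome medians followed those of the red pulp macrophage list from array to array, being -0.24, 0.12, -0.02 and 0.18 in wild type and 0.17, 0.06 and 0.27 in the hypomorph, against -0.54, 0.25, -0.22 and 0.50, and 0.28, 0.15 and 0.28. The CD11b lineage dendritic cell list followed them too, at -0.18, 0.06, -0.03 and 0.16 in wild type and 0.03, 0.07 and 0.34 in the hypomorph. Pearson r with the lysosome medians was 0.926 for the macrophage list and 0.906 for the CD11b lineage list. Without the arrays farthest out for each list, r was 0.473 and 0.716. The lysosome median was 0.28 without hypomorph replicate 2 and 0.11 without hypomorph replicate 3. That of autophagy was 0.09 without wild-type replicate 1, 0.07 without wild-type replicate 3 and 0.08 without hypomorph replicate 1, and with the mean over all probe sets of a gene the autophagy call was lost (adjusted p = 0.0574).

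The costimulation, NF-kB feedback, chemokine, and immediate early and heat shock lists ranked higher as well. Costimulation and maturation genes were positive in 17 of 20 cases, with a median of 0.10 (camera adjusted p = 0.0215, and adjusted p = 0.593 with an estimated correlation). They were led by Cd200 (0.27), Cd274 (0.69), which encodes the inhibitory ligand PD-L1, Cd80 (0.39) and Il15ra (0.29). NF-kB and A20 feedback genes were positive in 13 of 17 cases with a median of 0.07 (adjusted p = 0.0304, and 0.653 as the adjusted p with an estimated correlation), among them Tnfaip3 (0.56), Tnip2 (0.54), Rel (0.29) and Traf1 (0.25). Chemokine genes were positive in 15 of 19 cases with a median of 0.23 (adjusted p = 0.0131, and 0.593 as the adjusted p with an estimated correlation), led by Cxcl12 (0.89), Ccl6 (0.39), Cxcl1 (1.20) and Ccl2 (0.23). Immediate early and heat shock genes were positive in 15 of 25 cases with a median of 0.10 (adjusted p = 0.0469, and 0.653 as the adjusted p with an estimated correlation), with Klf6 (0.26), Rgs1 (0.46) and Hspb1 (0.45) above and Ier3 (-0.30) below. Adjusted over the list alone, 0 members of these lists passed. Without hypomorph replicate 1 the preset call was lost for costimulation (adjusted p = 0.260), NF-kB feedback (adjusted p = 0.250) and chemokines (adjusted p = 0.263, median 0.01). The NF-kB call was also lost without hypomorph replicate 3, wild-type replicate 1 or wild-type replicate 4 (adjusted p = 0.241, 0.129 and 0.0924), and the immediate early call without hypomorph replicate 2 or 3 (0.172 and 0.336) or wild-type replicate 1 or 4 (0.0806 and 0.189).

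The calls of the costimulation, NF-kB feedback, chemokine and immediate early lists also changed with other settings. The costimulation call was lost with the replicate block (adjusted p = 0.0970), with the mean over all probe sets of a gene (0.0501), without the 2 wild-type arrays richest in acinar transcripts (0.0641) and with the acinar level as a covariate (0.116). The chemokine call was lost in both acinar settings (adjusted p = 0.0841 and 0.119), which were chosen after the data were seen, and the NF-kB call with the block (0.0970). The immediate early call was lost with array weights (adjusted p = 0.148), the block (0.0915), 32 added to the linear value (0.0536), the mean over probe sets (0.0620) and both acinar settings (0.0771 and 0.0674). Single arrays moved the medians as well. Costimulation was at 0.06 without wild-type replicate 4 and 0.18 without hypomorph replicate 2, NF-kB feedback at 0.11 without wild-type replicate 2, 0.17 without hypomorph replicate 2 and 0.02 without hypomorph replicate 3, and chemokines at 0.15 without wild-type replicate 1. Immediate early genes were at 0.03 without wild-type replicate 1, 0.17 without wild-type replicate 3, 0.21 without hypomorph replicate 1 and 0.05 without hypomorph replicate 3.

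Cell cycle genes ranked lower, with all 30 measured members negative and a median log2 change of -0.32 (camera adjusted p = 3.05e-12, and adjusted p = 0.653 with an estimated correlation). Aurkb (-0.41), Cdc20 (-0.40), Top2a (-0.43) and Mcm5 (-0.42), genes of mitosis and DNA replication, had the smallest p, and 0 passed when adjusted over the list alone. The hypomorph arrays differed among themselves, with list medians of -0.40, 0.05 and -0.67 relative to the wild-type mean, while the wild-type arrays lay between -0.09 and 0.10. Without hypomorph replicate 2 the median was -0.51 and without hypomorph replicate 3 it was -0.15. The erythroid list, which shares no gene with the cell cycle list, moved with it, at -0.67, 0.45 and -1.90 on the same hypomorph arrays (Pearson r = 0.969 over the 7 arrays, exact permutation p = 0.000397). Oxidative phosphorylation genes were negative in 35 of 47 cases with a median of -0.05 (adjusted p = 0.00154, and 0.653 as the adjusted p with an estimated correlation), among them Ndufv1 (-0.22), Atp5a1 (-0.21), Cyc1 (-0.25) and Atp5c1 (-0.14). Adjusted over the list alone 0 passed, and without hypomorph replicate 3 the preset call was lost (adjusted p = 0.172, median -0.03). The median was -0.03 without wild-type replicate 1 and -0.09 without hypomorph replicate 1.

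Of the cell type lists, the basophil and mast cell list had the clearest members. In it, 8 of 10 measured genes were lower, with a median of -0.53 (camera adjusted p = 1.20e-05, and adjusted p = 0.593 with an estimated correlation), and the medians of the 3 hypomorph arrays were -0.43, -0.45 and -0.57, while the wild-type arrays ran from -0.30 on replicate 3 to 0.35 on replicate 4. Adjusted over the list alone, 4 members passed, namely Fcer1a (-1.76), Cpa3 (-1.06), Mcpt8 (-1.61), which encodes a basophil protease, and Hdc (-0.82), the histamine-producing decarboxylase. Mcpt8 read 8.26 ± 0.782 in wild type and 6.66 ± 0.0459 in the hypomorph, 3.05-fold lower. The stroma and endothelium list ranked higher, with 13 of 16 genes positive and a median of 0.39 (adjusted p = 1.20e-05, and 0.593 as the adjusted p with an estimated correlation). Adjusted over the list alone 2 passed, Igfbp7 (0.82) and the endothelial adhesion gene Pecam1 (0.42), followed by Cdh5 (0.52) and Sparc (0.64). Only 6 of the 16 stroma and endothelium genes were above the median of every array. Igfbp7, Pecam1 and Sparc were among them, but Cdh5 read 3.80 to 4.77, and Col1a1, Lum and Tek read between 2.72 and 3.11. The plasma cell list was positive in 11 of 12 cases with a median of 0.38 (adjusted p = 6.44e-05, and 0.593 as the adjusted p with an estimated correlation). It was led by Irf4 (0.33), Prdm1 (0.42), which encodes the plasma cell regulator Blimp-1, Sdc1 (0.62) and Jchain (0.75), and 0 passed when adjusted over the list alone.

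The neutrophil list was negative in all 15 measured genes with a median of -0.53 (camera adjusted p = 3.23e-06, and adjusted p = 0.593 with an estimated correlation). Elane (-0.63), Prtn3 (-0.52), Camp (-0.69) and Ngp (-0.37), which encode granule proteins, had the smallest p, and the hypomorph arrays had medians of -0.65, -0.69 and 0.06. With the acinar level as a covariate, a setting chosen after the data were seen, the neutrophil call was lost (adjusted p = 0.173, median -0.25), and without hypomorph replicate 1 the median was -0.24. Erythroid genes had a median of -0.70 with 15 of 17 negative (adjusted p = 0.000925, and 0.653 as the adjusted p with an estimated correlation), among them Car1 (-0.60), Gata1 (-0.88), Bpgm (-0.43) and Ermap (-0.70). Their medians were -0.67, 0.45 and -1.90 on the hypomorph arrays, and without hypomorph replicate 3 the call was lost (adjusted p = 0.532, median -0.12), while without hypomorph replicate 2 the median was -1.26. B cell genes were negative in 10 of 13 cases with a median of -0.16 (adjusted p = 0.0304, and 0.653 as the adjusted p with an estimated correlation), led by Cd79a (-0.52), Blk (-0.27), Ms4a1 (-1.09) and Cr2 (-0.20). Cd79a, Blk and Cr2 read between 3.24 and 4.35, below the median of every array. The B cell call was lost without hypomorph replicate 1 (adjusted p = 0.447, median -0.02), hypomorph replicate 2 (0.134), or wild-type replicate 2 or 3 (0.113 and 0.0748), and without wild-type replicate 1 the median was -0.24. It was also lost without the lowest 40% of probe sets (adjusted p = 0.130), with 32 added (0.0512), without the 2 wild-type arrays richest in acinar transcripts (0.109) and with the acinar covariate (0.741, median -0.05). Red pulp macrophage genes were positive in 18 of 19 cases with a median of 0.24 (adjusted p = 0.00372, and 0.703 as the adjusted p with an estimated correlation), with Mrc1 (0.30), Vcam1 (0.25), C1qc (0.39) and C1qa (0.33) first. That call was lost without wild-type replicate 1 (adjusted p = 0.340, median 0.01) or wild-type replicate 3 (0.0694, median 0.12), and without wild-type replicate 4 the median was 0.42. Adjusted over the list alone, 0 members of these 4 lists passed.

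**Figure D2:**
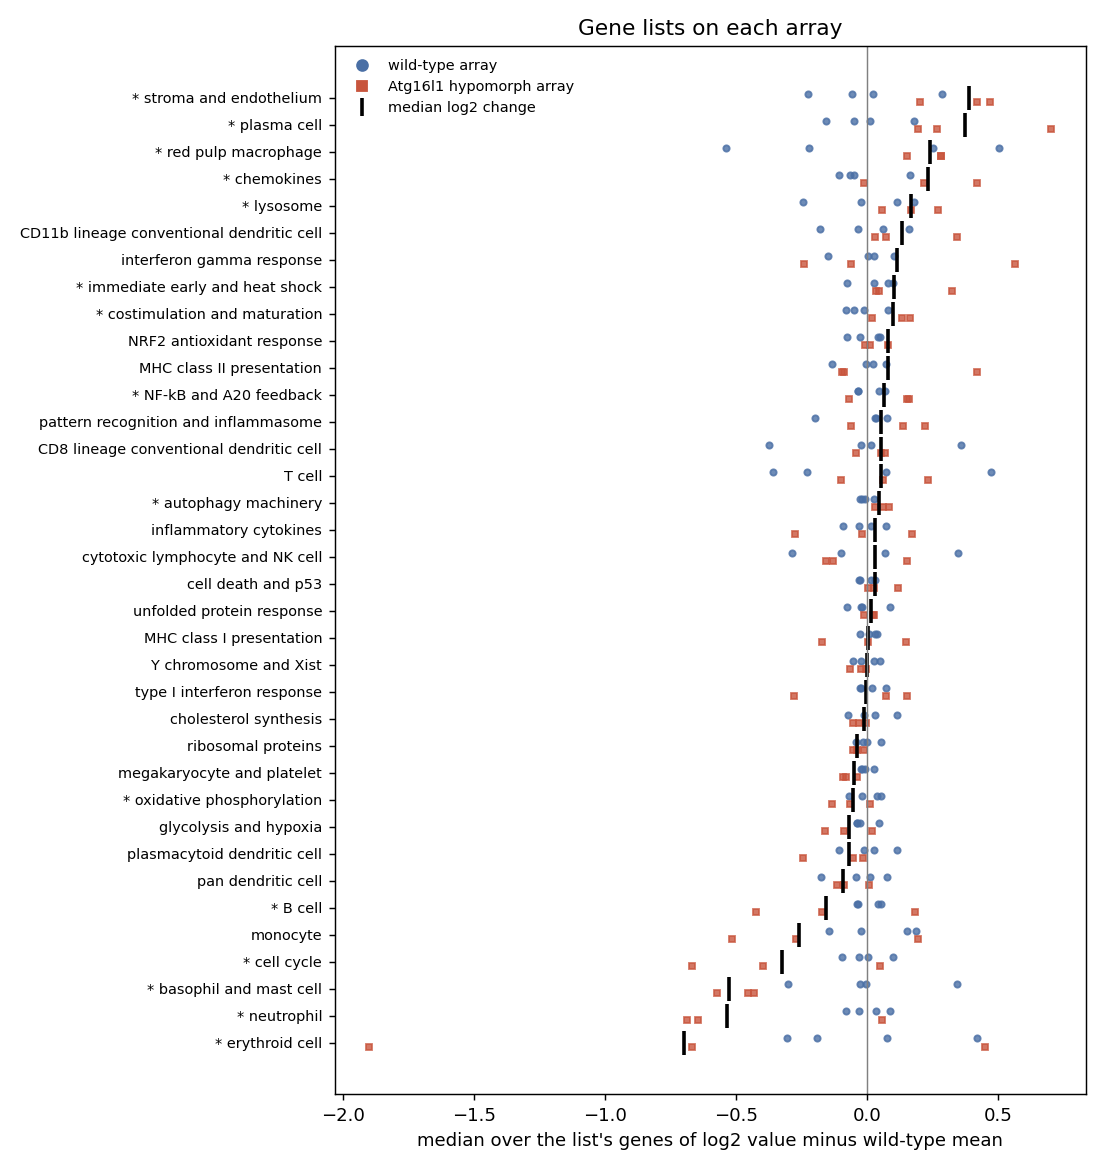
Median over each list's genes of the log2 value minus the wild-type mean, for each wild-type array (circles) and each Atg16l1 hypomorph array (squares), with the median log2 change as a black bar and an asterisk on the 15 lists called by camera with the preset correlation. The hypomorph arrays spread widely for the erythroid list, from -1.90 to 0.45, and closely for the basophil and mast cell list, from -0.57 to -0.43, where the wild-type arrays spread from -0.30 to 0.35.

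The lists that identify dendritic cells did not pass with all arrays and the deposited values, although some did in other settings. The pan dendritic cell list had a median of -0.09 (camera adjusted p = 0.242), with Cd24a at -0.55 and Zbtb46, a transcription factor of conventional dendritic cells, at -0.33. The CD8 lineage list had a median of 0.05 (adjusted p = 0.604, and 0.865 as the adjusted p with an estimated correlation). The CD11b lineage list had a median of 0.14 (adjusted p = 0.0577, and 0.653 as the adjusted p with an estimated correlation). It was led by Irf4 (0.33), which is also on the plasma cell list. The plasmacytoid list had a median of -0.07 (adjusted p = 0.238), and its member Ly6d (-0.52) passed when adjusted over the list alone (adjusted p = 0.0118). T cell, cytotoxic lymphocyte and NK cell, monocyte, and megakaryocyte and platelet lists had medians of 0.05, 0.03, -0.26 and -0.05, with adjusted p from 0.238 to 0.752. The calls given next for other settings all used the preset correlation. Several calls changed when 1 array was left out. The pan dendritic cell list was called lower without wild-type replicate 2 (median -0.15, adjusted p = 0.0308), and the CD8 lineage list higher without wild-type replicate 4 (0.14, adjusted p = 0.0484). The CD11b lineage list was called higher without wild-type replicate 2 (0.12, adjusted p = 0.0378), wild-type replicate 4 (0.20, adjusted p = 0.00786) or hypomorph replicate 1 (0.22, adjusted p = 0.0116). The T cell list was called higher without wild-type replicate 1 (0.22, adjusted p = 0.000110) or hypomorph replicate 3 (0.14, adjusted p = 0.0290), and the monocyte list lower without hypomorph replicate 3 (-0.42, adjusted p = 0.000737). Other single arrays moved these medians the other way: pan dendritic to -0.01 without wild-type replicate 3, CD11b lineage to 0.05 without hypomorph replicate 3, and monocyte to -0.11 without hypomorph replicate 1. The plasmacytoid and cytotoxic medians were -0.17 and 0.13 without hypomorph replicate 3, and the megakaryocyte median was -0.08 without hypomorph replicate 2 and -0.03 without wild-type replicate 3. Signs changed too. The CD8 lineage median was -0.06 without wild-type replicate 1, the plasmacytoid median 0.03 without hypomorph replicate 2, and the T cell median -0.04 without wild-type replicate 2, -0.03 without wild-type replicate 4 and -0.02 without hypomorph replicate 2. The cytotoxic lymphocyte and NK cell median was -0.10 without wild-type replicate 2 and -0.13 without hypomorph replicate 2. In the acinar settings the T cell median was -0.19 and the cytotoxic median -0.18 with the covariate, and the pan dendritic and plasmacytoid medians were 0.03 and 0.05 without the 2 arrays. The megakaryocyte median was 0.06 without the lowest 40% of probe sets. With the acinar level as a covariate, chosen after the data were seen, the CD8 lineage list was called higher (median 0.37, adjusted p = 0.000545), as was the CD11b lineage list (0.34, adjusted p = 0.000855). Without the 2 wild-type arrays richest in acinar transcripts their medians were 0.22 (adjusted p = 0.00383) and 0.23 (adjusted p = 0.00512), and with the replicate block 0.14 (adjusted p = 0.0485) and 0.20 (adjusted p = 0.00557). The medians with the block repeat those without wild-type replicate 4, because the block takes that array out of the comparison. The CD11b lineage list was also called higher without the lowest 40% of probe sets (0.17, adjusted p = 0.0147), and the monocyte list lower with array weights (-0.32, adjusted p = 0.0448). Transcripts of other cells were abundant on all arrays, since the neutrophil genes Ngp and S100a8 read at least 13.15 and 13.40 on each of them.

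The antigen presentation and interferon lists did not pass either. MHC class II genes had a median of 0.08 (camera adjusted p = 0.320), with the lysosomal processing genes Ctss and Ifi30 at 0.33 and 0.31. MHC class I genes had a median of 0.01 (adjusted p = 0.444), with the heavy chain genes H2-D1 and H2-K1 at 0.45 and 0.34. Type I interferon response genes had a median of -0.0046 (adjusted p = 0.801, and 0.927 as the adjusted p with an estimated correlation). Interferon gamma response genes had a median of 0.11 (adjusted p = 0.238, and 0.737 as the adjusted p with an estimated correlation), with Socs3 at 0.57. The antigen presentation and interferon calls, all made here with the preset correlation, depended on single arrays. Without hypomorph replicate 3 the type I list was called higher (median 0.11, adjusted p = 0.000248), as were the interferon gamma list (0.33, adjusted p = 0.00140) and the MHC class I list (0.09, adjusted p = 0.0267), whereas without hypomorph replicate 1 the interferon gamma list was called lower (-0.16, adjusted p = 0.0414). With array weights the interferon gamma list was called higher (0.22, adjusted p = 0.0283), and with the acinar covariate its median was -0.09. The MHC class II median was -0.10 without hypomorph replicate 1 and 0.17 without hypomorph replicate 2, the MHC class I median -0.08 without hypomorph replicate 1 and -0.02 without wild-type replicate 3, and the type I median -0.17 without hypomorph replicate 2. Inflammatory cytokine genes had a median of 0.03 and a mean of 0.05, whereas the camera direction was down (adjusted p = 0.841), and Il10 in this list had a change of 0.87. The median of this list was negative, from -0.05 to -0.01, without any 1 of wild-type replicates 1, 2 and 4 and hypomorph replicates 1 and 3. The unfolded protein response, NRF2 antioxidant, pattern recognition, and cell death lists had medians of 0.02, 0.08, 0.06 and 0.03, and the glycolysis, cholesterol synthesis and ribosomal protein lists -0.07, -0.01 and -0.04. Asns (-0.79), Srxn1 (0.39), Egln3 (-0.88), Fdps (-0.38) and Tlr8 (0.70) had the smallest p in their lists, and the adjusted p of these 7 lists ran from 0.122 to 0.430. The glycolysis list was called lower without hypomorph replicate 3 (-0.14, adjusted p = 0.0221), and the ribosomal protein list without wild-type replicate 4 (-0.04, adjusted p = 0.0482), with 32 added (-0.04, adjusted p = 0.00697) and with the acinar covariate (-0.06, adjusted p = 0.0217). The pattern recognition list was called higher in both acinar settings (0.13, adjusted p = 0.00512, without the 2 arrays, and 0.24, adjusted p = 0.000545, with the covariate), and its median was -0.02 without wild-type replicate 1 and 0.16 without hypomorph replicate 2. Over single arrays left out, the median ran from 0.01 to 0.06 for the unfolded protein response, 0.04 to 0.13 for NRF2, -0.0029 to 0.06 for cell death, -0.14 to -0.03 for glycolysis, -0.04 to -0.0035 for cholesterol synthesis and -0.04 to -0.02 for ribosomal proteins.

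Transcripts of pancreatic acinar cells, such as the chymotrypsinogen gene Ctrb1 and the elastase gene Cela3b, varied strongly between arrays. The mean log2 level of 17 such genes was 4.65, 5.61, 6.95 and 7.77 on the wild-type arrays and 4.12, 4.07 and 5.46 on the hypomorph arrays (exact permutation p = 0.114). Of these genes 16 were lower in the hypomorph, and Cela1 was higher by 0.30 and did not follow the others over the arrays (correlation -0.137). This list was drawn up after the data were seen. Without the pair of wild-type arrays with the highest level, replicates 3 and 4, the counts at an unadjusted p under 0.05 were 774 higher and 502 lower, and 0 probe sets passed the adjusted threshold.

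**Figure D3:**
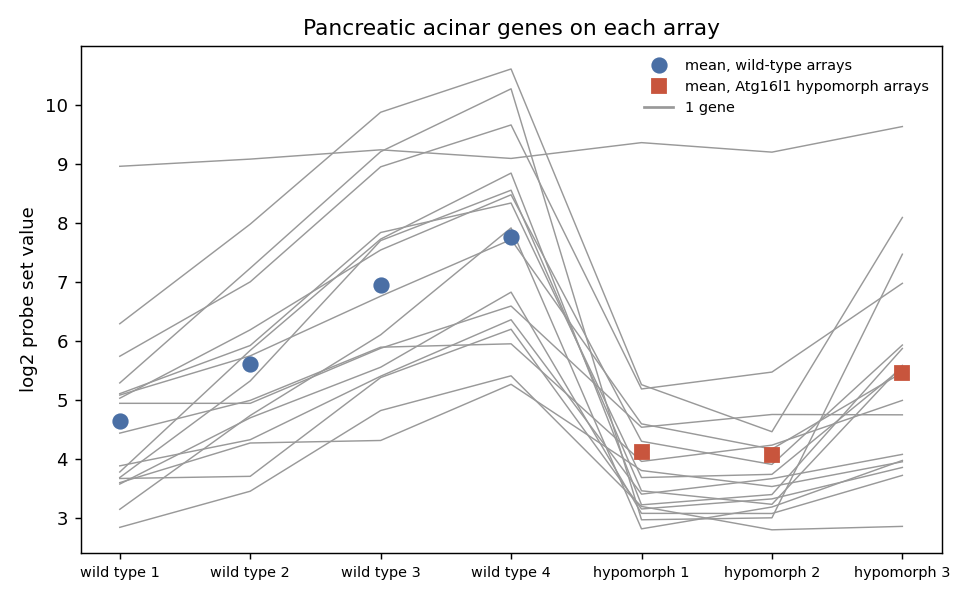
Log2 values of 17 pancreatic acinar genes on each array (grey lines, 1 per gene), with the mean over the genes as circles on wild-type arrays and squares on Atg16l1 hypomorph arrays. The means run from 4.07 to 7.77, and 1 gene, Cela1, stays at 8.96 or above on every array.

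**Figure D4:**
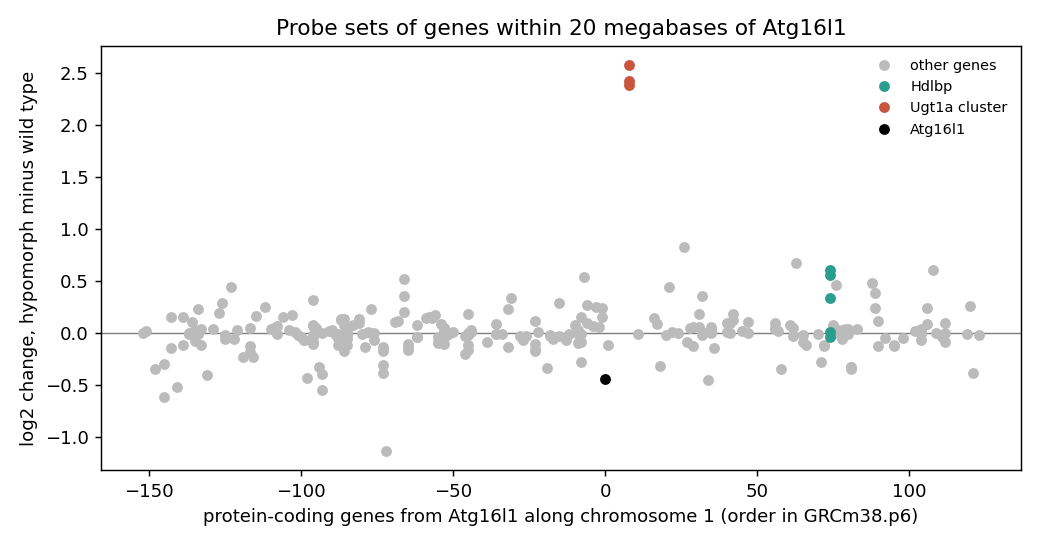
Log2 change (hypomorph minus wild type) of each probe set whose genes lie within 20 megabases of Atg16l1, by the number of protein-coding genes between it and Atg16l1 in the order of the GRCm38.p6 assembly. The 3 Ugt1a probe sets, drawn at the middle of their cluster, have log2 changes from 2.38 to 2.58, while Atg16l1 itself has -0.45.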

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

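The tests on the Ugt1a, basophil and acinar patterns were chosen after the results were seen, whereas the search for single arrays and control probe sets was planned. Among results with 4 wild-type values, 5 of 85 tested had 1 array far from the others, where chance gives 4.25. Il12b read 3.47 on wild-type replicate 2, with the other wild-type arrays between 3.30 and 3.32. Lamp2 read 10.08 on wild-type replicate 1 (others 10.34 to 10.38), and Tiam1 read 6.40 on the same array (others 6.65 to 6.70). The median deviation of the glycolysis and hypoxia list was 0.046 on wild-type replicate 4 (others -0.037 to -0.027), and that of the pattern recognition and inflammasome list was -0.197 on wild-type replicate 1 (others 0.033 to 0.078).

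Of the 64 control probe sets, which the comparison did not use, 4 were above all wild-type arrays on all hypomorph arrays, where chance gives 1.83, and 0 were below. They were the 3' probe set of 18S ribosomal RNA, higher by 0.317, and the 3', 5' and middle probe sets of beta-actin, higher by 0.0693, 0.160 and 0.115. The 3' minus 5' difference, which grows with RNA degradation, was 0.102 in the hypomorph and 0.202 in wild type for Gapdh and 0.384 against 0.475 for beta-actin (exact permutation p = 0.0857 for each). For the transferrin receptor it was 1.91 in the hypomorph and 2.01 in wild type (exact permutation p = 0.6).

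The Ugt1a probe sets were higher in the hypomorph by a mean of 2.46, and 1 of the 35 splits, the real one, gave a difference as large, the highest of the others being 1.93, which does not exclude chance, because the probe sets were picked for this difference out of 22625 and their adjusted p, 0.0694 to 0.0826, did not pass. RNA from liver or gut cells is argued against, since 18 measured genes of these tissues had a median log2 change of 0.0227 with an SD of 0.104, none of them above the median of every array, the highest being Lgals4 at 5.51. A xenobiotic or oxidative signal that raises the listed targets about as much as Ugt1a is argued against as well, but only for targets well above the lowest values. The 16 other targets, of which 7 are on another list, had a median of 0.207 with an SD of 0.304 and a maximum of 0.60 for Cyp1b1. Only 8 of them were above the median of every array. Cyp1a1, Cyp1a2, Aldh3a1 and Ahrr had wild-type means from 2.53 to 3.36, too low to tell much. Signals that act on targets outside the list were not tested. A smaller contribution stays open, with exact permutation p = 0.0286 for the median, the smallest possible, and 0.400 for the mean level. Sequence from another strain flanking the targeted allele may be the source and cannot be told apart from an effect of the genotype: without Atg16l1 and Ugt1a, 267 probe sets of genes within 20 megabases were not shown to differ more than others (difference -8.40e-05, highest other split 0.00905, exact permutation p = 0.457), nor were 160 within 10 megabases (difference 0.00693, highest other split 0.00963, exact permutation p = 0.114). The first difference met the bound of under 0.005 set against this explanation but not by more than the SD over the other splits, 0.00551, and the second did not meet it, both being conditions added after the bound had been met, and the bound was wrongly chosen by design, because the flank is inherited with the allele, its length is unknown, and it can alter 1 cluster and leave most neighbours alone.

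The basophil and mast cell list differed by a median of 0.527 in size, being lower in the hypomorph, and 1 of the 35 splits, the real one, moved it as far in either direction, the highest of the others being 0.526 (wild-type replicates 1, 2 and 4 against the rest), which does not exclude chance, because the list was picked from 36 for its values and was not called with an estimated correlation (adjusted p = 0.593). None of its 10 measured genes is on another list, 5 were above the median of every array, and its highest value was 9.34 for Mcpt8. Eosinophil genes, a list drawn up after the data were seen, had a similar median of -0.49, with changes from -0.96 to -0.02. They were not shown to differ between the groups (exact permutation p = 0.114 for the median). Fewer carried-over cells of every kind would lower all 11 lists of non-dendritic cells. Of these lists 6 were lower, among them neutrophil (-0.53), erythroid (-0.70), monocyte (-0.26) and B cell (-0.16). The other 5 were higher, among them plasma cell (0.38), stroma (0.39) and red pulp macrophage (0.24), which a loss of every kind would not give. However, none of these rises was called with an estimated correlation, so the explanation is not excluded. The SD of the 11 medians, 0.372, was reached by other splits (highest 0.384, exact permutation p = 0.0857). It measures how far the lists differ from each other, so it does not decide on a common loss. Fewer basophils in the spleen, fewer of them kept by the CD11c sort (which would remove those that lack CD11c), and lower transcript levels per cell may each give this, and no measurement here separates them.

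Acinar transcripts differed between arrays by a mean level of 4.07 to 7.77 over 17 genes, of which 0 are on another list and 1, Cela1, was above the median of every array, the highest value being 10.6 for Ctrb1. Of the genes 16 rose and fell together (median pairwise correlation 0.952 over 7 arrays for all 17), with a median log2 change of -1.87, whereas Cela1 did not follow (correlation -0.137 with the mean of the others, at least 0.913 for each of the 16) and was higher in the hypomorph by 0.30. A set of 9 islet genes did not move together (correlation 0.0219, median change 0.0123). Of these islet genes 0 were above the median of every array, the highest value being 4.49 for Sst, so they were too low to tell much. Pancreatic tissue carried over with the spleen is a candidate source, although the CD11c sort would remove intact acinar cells, and free RNA is another route. Genotype cannot be told apart from it at 7 arrays (6.25 ± 1.39 in wild type and 4.55 ± 0.788 in the hypomorph, exact permutation p = 0.114, and 0.0857 for the median change).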

How the results depend on the processing

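Leaving out the 2 wild-type arrays with the most acinar transcripts and the acinar covariate were chosen after the results were seen, and the other alternatives were planned. The count of probe sets lower at the adjusted threshold stayed 0 in limma under every alternative run for it. The count higher, 0 as reported, was 5 after median centring (Pcmtd1, Cdk12 and the 3 Ugt1a probe sets), 5 with trend and robust settings (the same 5), 3 without the lowest 40% of probe sets and 3 with array weights (Pcmtd1, Cdk12 and the Ugt1a probe set with the smallest p in both), at adjusted p of 0.0430 to 0.0483. It was 0 after quantile normalization, with 32 added, with the block and under both acinar alternatives. Leaving out 1 array gave 0 to 2, namely 1 without wild-type replicate 3 (a probe set that names no gene), 1 without hypomorph replicate 1 and 2 without hypomorph replicate 2 (Ugt1a probe sets in both). Filtering tests fewer probe sets, and for the others the cause was not tested. At an unadjusted p under 0.05 the counts ranged over single arrays left out from 598 to 1411 higher and from 431 to 1578 lower, and the lower count was 502 without the 2 wild-type arrays and 1160 with the covariate. With the estimated correlation 0 lists were called higher and 0 lower, against 9 and 6; leaving out 1 array gave 7 to 11 and 5 to 7. Of the 15 called lists, 7 were called without each array and 5 (lysosome, cell cycle, plasma cell, basophil and mast cell, stroma and endothelium) in every alternative with the preset correlation. The interferon gamma list reversed to -0.16 without hypomorph replicate 1 (range over single arrays to 0.33), and the type I interferon list to 0.11 without hypomorph replicate 3 (range from -0.17); the cause was not tested. Atg16l1 was lower in all alternatives run for it, from -0.49 to -0.40 over single arrays left out. The chromosome 1 difference, 0.0268, was 0.0260 to 0.0314 with 1 array left out and 0.0303 without the 2 wild-type arrays, where the smallest exact p possible is above 0.05. It was 0.0512 at 10 megabases and 0.0528 without the lowest 40% of probe sets. Of 73 single results 17, none past the threshold, changed sign under at least 1 of 19 alternatives. The covariate and the block gave no chromosome 1 value. Signal over background could not be judged, since no detection calls were held.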

Other observations

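The tests on eosinophil, nuclear RNA, pairing and list correlation values were chosen after the results were seen, and those on chromosome 1 and on other splits were planned. Eosinophil genes were not shown to differ between the groups: 7 measured genes had a median log2 change of -0.49, from -0.96 for Epx to -0.02 for Ccr3 (exact permutation p = 0.114 for the median and 0.171 for the mean level). Prg2, which encodes eosinophil major basic protein, read 8.96 ± 0.448 (SD, n = 4) in wild type and 8.14 ± 0.828 (SD, n = 3) in the hypomorph. Nuclear retained RNAs had a median of 0.0162, with Malat1 at 12.1 in wild type and 12.6 in the hypomorph and Neat1 at 8.65 and 9.32 (exact permutation p = 0.886 for the median and 0.286 for the mean level).

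Genes on chromosome 1 within 20 megabases of Atg16l1 differed more than others by 0.0268 in mean absolute log2 change over 271 probe sets (highest other split 0.0252, exact permutation p = 0.0286, the smallest possible). The planned Fisher test on called probe sets had no outcome, because 0 were called. Without Atg16l1 and Ugt1a the difference was -8.40e-05 (exact permutation p = 0.457), and within 10 megabases without them 0.00693 (exact permutation p = 0.114). Hdlbp, 74 protein-coding genes away, and Pcmtd1 lie on chromosome 1, and Cdk12 lies on chromosome 11.

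Of the 35 splits of the arrays into 4 and 3, all 35 gave at least the 0 probe sets that the real split gave at a limma adjusted p under 0.05 (highest other 0), which a count of 0 makes certain and which therefore says nothing about chance. A count of probe sets at an unadjusted p under 0.05 as large as 1739 came from 4 splits, with 2047 the highest of the others. As many lists higher as 9 came from 6 splits (highest other 11), and as many lower as 6 from 18 splits (highest other 11). Chance is not excluded for the counts at an unadjusted p and of lists.

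The medians of the cell cycle and lysosome lists on the 7 arrays were set against those of the 15 cell type lists, 30 relations in all, none with shared genes in the pairs named here. Cell cycle followed erythroid cells (Pearson r = 0.969, exact permutation p = 0.000397, adjusted p = 0.0119; Spearman rho = 0.964, exact permutation p = 0.00278, adjusted p = 0.0417), with r = 0.927 without hypomorph replicates 2 and 3, the arrays farthest out. Lysosome followed red pulp macrophages (r = 0.926, exact permutation p = 0.00496, adjusted p = 0.0640; rho = 0.964, exact permutation p = 0.00278, adjusted p = 0.0417), but r was 0.473 without wild-type replicates 1 and 3, so this relation rests on those arrays. Lysosome also followed the CD11b lineage dendritic cell list (r = 0.906, exact permutation p = 0.00694, adjusted p = 0.0640). For this pair rho was 0.857 (exact permutation p = 0.0238, adjusted p = 0.179). Without wild-type replicate 1 and hypomorph replicate 3, the arrays farthest out for that list, r was 0.716. The arrays do not show which cells carry the cell cycle and lysosome transcripts.

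All 7 arrays carried Xist between 8.76 and 11.9, and the Y-linked genes Kdm5d, Eif2s3y and Uty between 2.13 and 2.68. The Y chromosome and Xist list had a median of -0.00015 (camera adjusted p = 0.801). The deviations of arrays with the same replicate number from their group means correlated at 0.102, 0.0977 and 0.339, but hypomorph replicate 1 correlated best with wild-type replicate 2 (0.207) and hypomorph replicate 2 with wild-type replicate 1 (0.126), so the numbers gave no pairing.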
